A study of Drosophila melanogaster with 9 samples.

How the data were processed

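Mesodermal cells of Drosophila embryos were isolated by fluorescence-activated sorting for green fluorescent protein, which twi-GAL4 driving UAS-2EGFP places in cells that express Twist, and their total RNA was hybridised to Affymetrix Drosophila expression arrays with 1 biotin-labelled sample per array. Embryos were aged at 25 °C to stage 11 or early stage 12, and about 2 to 5 µg of total RNA was labelled per sample, per the labels' protocols. The 9 arrays fall into 3 groups of 3. The first held embryos homozygous for the CHES-1-like null deletion Df(1)CHES-1-like1. The second held embryos homozygous for the deficiency Df(3R)Exel6157, a jumu null per the labels. Control embryos carried twi-GAL4 and UAS-2EGFP and neither deletion. The titles place driver and reporter on different homologues in the jumu deficiency, each with the deficiency, and write them together in the other groups. Arrangement or copy number of these transgenes may therefore differ between the groups. Nothing in the labels says that replicates came from separate embryo collections or sorts, so p-values measure the spread between these arrays, which may be technical.

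The deposited values are log2 signals per probe set, as their range of 2.99 to 14.89 shows, with array medians between 5.41 and 5.50. The nearly equal distributions show that the arrays had been normalized to each other. The submitters' processing notes name the R package affy. Its version, the background correction, the summary method and any filter are not given in the sources used here. A signal summarised over a probe set saturates at the top, flattens near background and can include cross-hybridisation, so fold changes of dim genes are understated and levels of different probe sets cannot be compared. As an empirical background, the 125 probe sets of odorant and gustatory receptor genes had a median of 4.15 and a 95th percentile of 5.28, and a fold change against a group mean below that percentile understates the change. The number of arrays limits the precision.

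Of 18952 probe sets, 183 array controls were left out and 18769 were tested. In the platform annotation given, 13647 of these had 1 gene, 402 had several and 4720 were not listed, and the last 2 kinds were not named. Symbols were updated through the gene identifier to the annotation of Release 6 plus ISO1 MT for 13544 probe sets, and 103 kept the older symbol. That annotation was used only for names and for the order of neighbouring genes, since no genome build is given for the arrays. The 11982 genes are each represented by the probe set of highest mean over the 9 arrays, and 1094 genes had several. Genes without a named probe set were not analysed here.

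Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 9 arrays, which share 1 estimate of the spread with 6 residual degrees of freedom, and the contrasts were CHES-1-like null minus control, jumu deficiency minus control, and jumu deficiency minus CHES-1-like null. Adjusted p-values are Benjamini-Hochberg values from limma over all probe sets tested, with a threshold of 0.05. Changes are log2 differences with the standard error (SE) of the fit, and group means carry the standard deviation (SD). The comparisons of the report, the gene lists, the rule for named genes and the alternatives listed here were fixed before the data were examined, and tests or alternatives chosen later are named where they are given.

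The 24 gene lists covered the FGF receptor and Ras MAPK, Wnt, Dpp and Tgf-beta, Notch and Hedgehog pathways, cardiac mesoderm, somatic muscle founder and fusion genes, muscle structural genes, visceral mesoderm, haemocyte and fat body, gonadal mesoderm, neural cells, epidermis, trachea and salivary gland, endoderm, germ cells, early embryo patterning, cell division, the Forkhead family, heat shock and dissociation stress, dosage compensation and sex, cytosolic ribosomal proteins, Hox genes and cofactors, and cell adhesion and matrix. Of 737 listed symbols, 539 had a named probe set, some in several lists. Each list was tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. An estimated correlation and fry were alternatives. The named genes are, per comparison, the targeted genes and htl, the 8 highest and 8 lowest changes past the threshold whose arrays did not overlap between the groups, up to 4 members of smallest p from each list, and the 5 genes per direction of largest mean change shared by both mutants. The neighbours Rfx, Bruce, CG31406, Pdp and ct were named after their values were seen.

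Alternatives were quantile normalization, centring each array on its median, leaving out the lower 40% of probe sets by mean signal, the replicate number as a block, fitting only the groups compared, a variance trend with robust estimation, array weights, a threshold of 0.01, a minimum change of 1.5-fold, the mean of a gene's probe sets, leaving out each array, Welch's test, and leaving out the deleted neighbours. The fit was tested on simulated data: with 200 of the 18769 probe sets changed, 77.6% of the 1.5-fold and 98.5% of the 2-fold changes were recovered for CHES-1-like null minus control, 88.1% and 100% for jumu deficiency minus control, and 88.1% and 98.5% for jumu deficiency minus CHES-1-like null. Of the smallest changes simulated, 0.32 on the log2 scale, 52.2%, 43.3% and 52.2% were recovered in the same order. The median size of the called changes in the data was 0.32, 0.33 and 0.36. In the data 29%, 32.2% and 34.4% of probe sets were called, so the Benjamini-Hochberg adjustment was stricter in the simulation. The shares recovered therefore do not carry over to the data. Of the simulated calls, 2.56%, 5.52% and 5.36% were false in the same order. Among 23 unmoved simulated lists, camera called 1 in the direct comparison.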

Results

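Expression profiles of sorted mesodermal cells were compared between embryos that lack CHES-1-like, embryos with a deficiency that the labels call a jumu null, and controls, with 3 arrays in each group. CHES-1-like and jumu encode Forkhead transcription factors, and the study concerns their part in specifying cardiac progenitors through receptors for fibroblast growth factor (FGF) and Wnt. Arrays of a group correlated at Pearson's r of 0.998 to 0.999 across probe sets, against 0.991 to 0.993 between the CHES-1-like null and control arrays and 0.987 to 0.988 between the jumu deficiency and control arrays. Replicate 3 of the CHES-1-like null was the array least correlated with its own group.

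The targeted genes were examined first in every array. CHES-1-like signal was 12.01 ± 0.03 (SD, n = 3) on the log2 scale in controls and 4.04 ± 0.25 in the CHES-1-like null. The null level lies within the background of the chemoreceptor probe sets, and the 3 null arrays read 3.88, 4.32 and 3.92. A second probe set of CHES-1-like fell by 1.80 ± 0.20 (SE) in the null. In the jumu deficiency, jumu fell by 2.39 ± 0.07 (SE), to 19.0% of the control signal (limma adjusted p = 1.24e-08). The jumu signal of 8.13 ± 0.12 (SD, n = 3) in the deficiency stayed above the 5.28 that bounds 95% of the chemoreceptor probe sets, with array values of 8.18, 8.21 and 7.99. Whether this probe set lies inside the deleted interval was not checked, so the remaining signal leaves the loss of jumu in these samples unsettled. CHES-1-like was also lower in the jumu deficiency, by −0.61 ± 0.13 (SE, limma adjusted p = 0.00557), although its second probe set did not pass the threshold (−0.53, adjusted p = 0.0759). The change of jumu in the CHES-1-like null was 0.15 ± 0.07 (adjusted p = 0.127).

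Genes next to jumu along the chromosome were examined because a deficiency can remove neighbours. Rfx, the nearest measured gene on one side, fell by 2.10 ± 0.08 (SE) from 6.32 ± 0.09 (SD, n = 3) to 4.22 ± 0.14, within the background, and it was the sole neighbour in the unbroken run of lower genes around jumu. Bruce, a few genes away on the other side, rose by 3.40 ± 0.05 (SE) to 13.04 ± 0.06 (SD, n = 3). CG31406, the nearest on that side, rose by 1.12 ± 0.10 (SE), from 4.105 ± 0.094 (SD, n = 3) to 5.224 ± 0.222. Both means of CG31406 lie within the background, so its rise does not settle whether the deficiency removes it. Among the 20 measured neighbours of jumu, 6 were lower, 7 were higher and 7 did not pass the threshold. Without replicate 2 of the jumu deficiency the run held 2 neighbours. Around CHES-1-like no neighbour belonged to such a run, and of 20 neighbours 3 were lower, among them Pdp at −0.39 ± 0.04, and ct was higher at 0.46 ± 0.08.

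**Figure D1:**
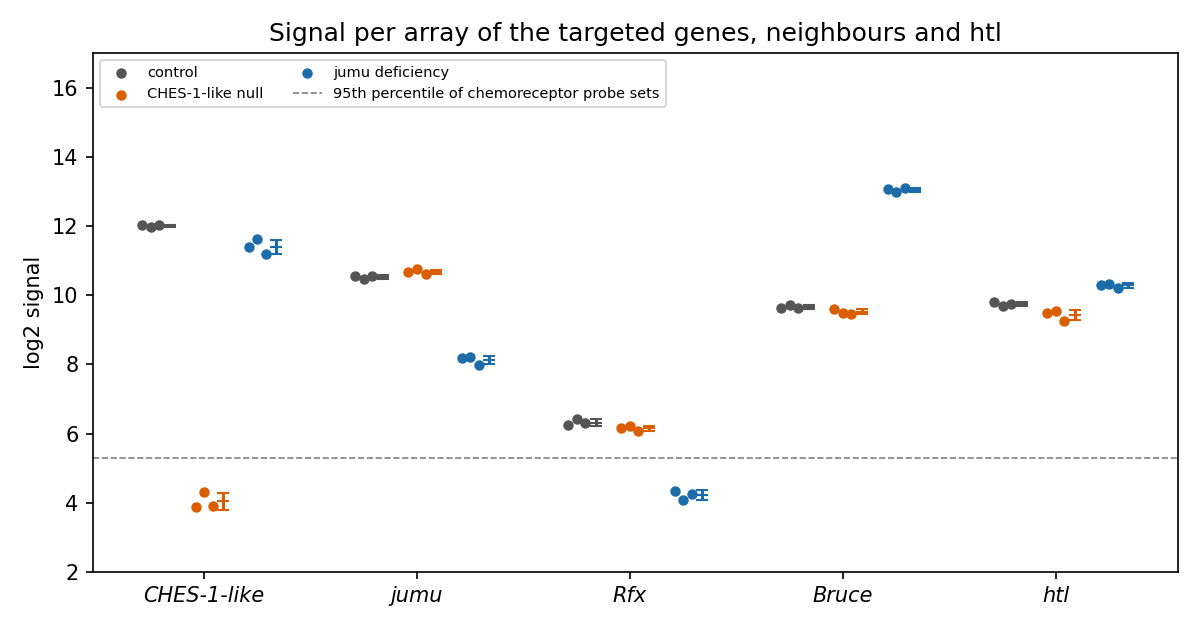
Log2 signal on each array of the targeted genes CHES-1-like and jumu, the jumu neighbours Rfx and Bruce, and htl, for control, CHES-1-like null and jumu deficiency, with points for the 3 arrays of a group, bars for mean ± SD and a dashed line at the 95th percentile of chemoreceptor probe sets. The CHES-1-like null arrays lie below the line for CHES-1-like, and jumu falls from 10.52 to 8.13 in the deficiency.

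The series title names receptors of the FGF and Wnt pathways, and the FGF receptor gene of the mesoderm, htl, moved in opposite directions in the mutants. It fell by 0.32 ± 0.07 (SE) in the CHES-1-like null, from 9.75 ± 0.06 (SD, n = 3) to 9.43 ± 0.15 (limma adjusted p = 0.0096), and rose by 0.53 ± 0.07 in the jumu deficiency, to 10.28 ± 0.06 (adjusted p = 0.000473). The difference between the mutants was 0.85 ± 0.07 (adjusted p = 1.67e-05). In each comparison the arrays of the groups did not overlap. The same held for 42.7% of all probe sets in the CHES-1-like null, 46.8% in the jumu deficiency and 43.6% between the mutants. Since htl was chosen from what the study names, its change is not independent evidence. The Wnt receptor gene fz was not analysed here. The other FGF receptor gene, btl, known for tracheal branching, rose in both mutants, by 0.88 ± 0.07 in the CHES-1-like null and 1.73 ± 0.07 in the jumu deficiency.

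In the CHES-1-like null the muscle structural list was lower, and the epidermis, trachea and salivary gland, neural and cell division lists were higher at the preset correlation. These higher calls were lost with adjusted p = 0.0713, 0.0894, 0.229 and 0.126 with an estimated correlation. Of 23 measured muscle structural genes 13 fell and 1 rose (camera adjusted p = 5.58e-06, and adjusted p = 0.0479 with an estimated correlation). The decreases included the myosin light chain gene Mlc1 at −0.95 ± 0.04 (SE), the tropomyosin gene Tm2 at −0.91 ± 0.05 and the muscle LIM protein gene Mlp60A at −0.73 ± 0.05, for which 1 of 2 further probe sets did not pass. Among 34 genes of muscle founders and fusion 14 fell and 8 rose (camera adjusted p = 0.0145, and adjusted p = 0.119 with an estimated correlation). The fusion receptor gene sns fell by 0.88 ± 0.04, and the fusion genes rols, Vrp1 and blow changed by −0.65 ± 0.04, −0.76 ± 0.05 and −0.66 ± 0.04. With p adjusted over the list alone, 17 structural genes were lower and 3 higher. For founder and fusion genes these counts were 16 and 8. Without the dim probe sets the founder and fusion list gave adjusted p = 0.0614. Without replicate 3 of the CHES-1-like null, an alternative added after the data were seen, 14 structural genes were lower and 2 higher, and 14 founder and fusion genes were lower and 8 higher.

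Markers of cell types outside the mesoderm rose in the same arrays. In the epidermis list 23 of 33 genes rose and 2 fell (camera adjusted p = 4.87e-07, and adjusted p = 0.0713 with an estimated correlation), among them the septate junction claudin gene sinu at 0.79 ± 0.05 (SE) and the chitin deacetylase genes serp at 0.70 ± 0.04 and verm at 0.63 ± 0.04. The polarity gene sdt rose by 0.82 ± 0.05 at its brightest probe set, whereas 4 of its 5 further probe sets did not pass. In the trachea and salivary gland list 15 of 23 rose and 1 fell (adjusted p = 1.42e-05, and adjusted p = 0.0894 with an estimated correlation), with pio at 1.03 ± 0.05, of whose 2 further probe sets 1 did not pass. In the neural list 19 of 33 rose (adjusted p = 0.000223, and adjusted p = 0.229 with an estimated correlation), including the transcription factor genes grh at 0.85 ± 0.06, sc at 0.75 ± 0.07 and D at 0.56 ± 0.04. The lists overlap: grh is also in the epidermis list, and serp and verm are also in the trachea and salivary gland list. Their rises are therefore not separate evidence for each cell type. In the endoderm list 6 of 11 rose and 1 fell (adjusted p = 0.0378, and adjusted p = 0.136 with an estimated correlation), with peb at 0.58 ± 0.05 and Hnf4 at 0.51 ± 0.04. The endoderm call was lost without replicate 1 of the CHES-1-like null (adjusted p = 0.0607), without control replicate 3 (0.0553) and without the dim probe sets (0.055). Adjusted over the list alone, 25 epidermis, 16 trachea and salivary gland, 19 neural and 7 endoderm genes were higher, against 3, 1, 2 and 1 lower. Without replicate 3 of the CHES-1-like null, 22 epidermis, 15 trachea and salivary gland, 18 neural and 6 endoderm genes were higher.

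Cell division genes rose in 27 of 41 cases and fell in 3 in the CHES-1-like null (camera adjusted p = 5.54e-06, and adjusted p = 0.126 with an estimated correlation). The securin gene pim rose by 0.94 ± 0.05 (SE), the replication licensing gene dup by 0.66 ± 0.04 and the Cdc25 phosphatase gene twe by 1.18 ± 0.08. In the early embryo patterning list 14 of 27 rose and 1 fell (adjusted p = 0.00175, and adjusted p = 0.136 with an estimated correlation), with bcd at 0.73 ± 0.04 and kni at 0.82 ± 0.07, while hry fell by 0.51 ± 0.06. The counts adjusted over the list alone were 29 division genes higher and 4 lower. For patterning genes they were 14 and 2. Without replicate 3 of the CHES-1-like null the division list held 28 higher and 2 lower genes and the patterning list 12 and 2. Haemocyte genes went both ways. The crystal cell genes PPO1 and PPO2 changed by −0.84 ± 0.05 and −0.86 ± 0.04 and the growth factor receptor gene Pvr rose by 0.54 ± 0.04. Of the 29 genes in the haemocyte and fat body list 13 rose and 5 fell (adjusted p = 0.291), and 15 and 8 adjusted over the list alone.

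Across all probe sets, 2637 were higher and 2805 lower in the CHES-1-like null than in controls, of which 117 and 135 changed at least 2-fold. After centring each array on its median, 39.4% of the calls were higher (1965 higher and 3020 lower), against 48.5% as deposited. The largest increases were those of the lysozyme gene LysX at 2.69 ± 0.08 (SE), the guanylyl cyclase gene Gyc89Da at 2.67 ± 0.10, CG12637 at 2.48 ± 0.09 and nkt at 2.47 ± 0.08, and those of be, CG12885, the calcium sensor gene Frq2 and alpha-Est5 followed with 2.42, 2.36, 2.25 and 2.16. The largest decreases, CHES-1-like apart, were those of CG33337 at −5.85 ± 0.13, CG42324 at −3.88 ± 0.11, CG13003 at −3.81 ± 0.15 and the peptidoglycan receptor gene PGRP-LE at −3.53 ± 0.11. CG13794, boil, CG2233 and thw followed, at −3.15 to −2.69, though 1 of the 2 further probe sets of thw did not pass. Each limma adjusted p among these genes was at most 3.16e-06. By the rule for named genes, only genes whose arrays did not overlap between the groups were taken, which held for 42.7% of all probe sets.

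In the jumu deficiency, the haemocyte and fat body list was higher and the germ cell, cell division and muscle structural lists were lower at the preset correlation. The 4 calls were lost with adjusted p = 0.0635, 0.429, 0.441 and 0.28 with an estimated correlation. Of 29 haemocyte and fat body genes 16 rose and 1 fell (camera adjusted p = 7.51e-07, and adjusted p = 0.0635 with an estimated correlation). The collagen IV genes vkg and Col4a1 rose by 1.58 ± 0.05 (SE) and 1.17 ± 0.04, the secreted glycoprotein gene Glt by 1.52 ± 0.06 and the chitinase-like gene Idgf6 by 1.27 ± 0.04. In the germ cell list 10 of 16 fell and 1 rose (adjusted p = 0.00205, and adjusted p = 0.429 with an estimated correlation), including the piRNA pathway genes krimp at −2.79 ± 0.10, AGO3 at −1.60 ± 0.08 and aub at −0.92 ± 0.04. In the cell division list 23 of 41 fell and 8 rose (adjusted p = 0.0195, and adjusted p = 0.441 with an estimated correlation), with the cytokinesis gene tum at −0.995 ± 0.04, the kinesin gene ncd at −0.998 ± 0.05 and pim at −0.98 ± 0.05. Of 23 muscle structural genes 11 fell and 2 rose (adjusted p = 0.024, and adjusted p = 0.28 with an estimated correlation), with Mlp60A at −0.73 ± 0.05 and the actinin gene Actn at −0.54 ± 0.06. Adjusted over the list alone, 18 haemocyte and fat body genes were higher and 1 lower, 10 germ cell genes lower and 1 higher, 23 division genes lower and 10 higher, and 13 structural genes lower and 2 higher.

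These list calls in the jumu deficiency had limits. The division and structural calls were lost with quantile normalization (adjusted p = 0.0527 and 0.068) and without the dim probe sets (0.13 for both), and the structural call also after centring each array (0.0577). Without replicate 2 of the jumu deficiency 7 lists passed in place of 4. On the array control transcripts, the 3′ signal exceeded the 5′ signal by 1.26 ± 0.03 (SD, n = 3) for actin in the jumu deficiency against 1.04 ± 0.01 in controls and 0.94 ± 0.06 in the CHES-1-like null, and for eIF-4a by 1.35 ± 0.03 against 1.07 ± 0.07 and 1.15 ± 0.05. For GAPDH the differences were 0.42 ± 0.16, 0.34 ± 0.09 and 0.08 ± 0.25 in the same order, and for 18S ribosomal RNA 0.76 ± 0.05, 0.95 ± 0.05 and 0.81 ± 0.11.

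Mesodermal regulators in the jumu deficiency changed in both directions. Among 21 cardiac mesoderm genes 8 rose and 2 fell (camera adjusted p = 0.136), with the pericardial matrix gene prc at 2.01 ± 0.08 (SE) and the T-box genes Doc1, Doc2 and Doc3 at 0.39 ± 0.05, 0.35 ± 0.06 and 0.47 ± 0.05. In the CHES-1-like null 7 of these genes rose and 4 fell (adjusted p = 0.42), with the GATA gene pnr at 0.47 ± 0.04, and Him and Hand at −0.47 ± 0.04 and −0.50 ± 0.07. The visceral mesoderm genes bap and bin rose by 0.85 ± 0.06 and 0.43 ± 0.04 in the jumu deficiency, where 9 of 22 list members rose and 5 fell (adjusted p = 0.573), against 6 and 7 in the CHES-1-like null (adjusted p = 0.413). Adjusted over the list alone, 8 cardiac and 9 visceral genes were higher and 2 and 6 lower in the jumu deficiency, and 8 and 7 higher and 4 and 8 lower in the CHES-1-like null. The Hedgehog receptor gene ptc fell by 1.68 ± 0.06 in the jumu deficiency and fell by 0.47 ± 0.06 in the CHES-1-like null. In the FGF receptor and Ras MAPK list 11 of 24 rose and 4 fell in the jumu deficiency (adjusted p = 0.225) and 8 rose and 4 fell in the CHES-1-like null (adjusted p = 0.382), with kek1, an inhibitor of EGF receptor signalling, at −1.28 ± 0.08 and −1.46 ± 0.08. Of 17 measured Wnt pathway genes 6 rose and 3 fell in the jumu deficiency (adjusted p = 0.306) and 5 rose and 2 fell in the CHES-1-like null (adjusted p = 0.108). Without replicate 3 of the CHES-1-like null, 6 rose and 0 fell in that mutant. The glypican gene dlp rose in both mutants, by 0.50 ± 0.04 in the jumu deficiency and 0.56 ± 0.04 in the CHES-1-like null. The gene wls, which serves Wnt secretion, rose by 0.41 ± 0.04 and 0.35 ± 0.04 in the same order. As the study names these pathways, the counts in the FGF and Wnt lists are not independent evidence. For these lists, adjusted over the list alone, 11 and 6 genes were higher and 5 and 4 lower in the jumu deficiency, and 11 and 5 higher and 5 and 3 lower in the CHES-1-like null.

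**Figure D2:**
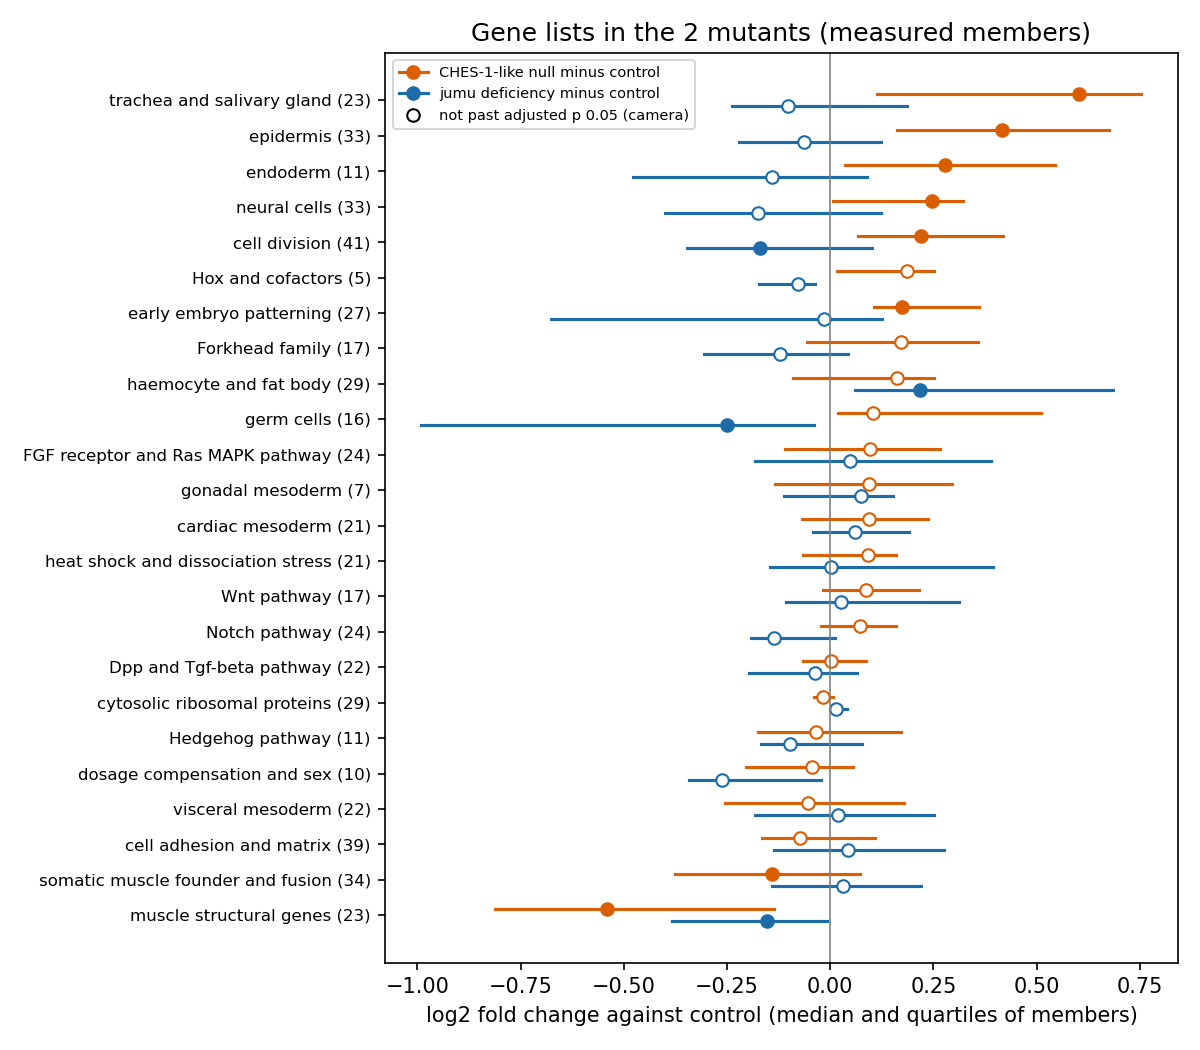
Median (points) and quartiles (lines) of the log2 fold change against control over the measured members of the 24 gene lists, in the CHES-1-like null (orange) and the jumu deficiency (blue), with open points for lists not past an adjusted p of 0.05 with camera and the number of measured members in brackets. The cell division list lies at 0.22 in the CHES-1-like null and at −0.17 in the jumu deficiency, and the muscle structural list lies below 0 in both.

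Across all probe sets, 2781 were higher and 3254 lower in the jumu deficiency than in controls, of which 254 and 204 changed at least 2-fold. After centring each array on its median, 31.4% of the calls were higher (1820 higher and 3974 lower), against 46.1% as deposited. The largest increases were those of the sodium channel family gene Nach at 7.24 ± 0.06 (SE), mwh at 5.42 ± 0.08, the gustatory receptor gene Gr98b at 5.40 ± 0.07 and mthl4 at 5.24 ± 0.05, and CG31176, beat-Ic, Gyc89Da and CG31601 followed with 4.63, 4.44, 4.33 and 4.10. A second probe set of mwh did not change past the threshold (−0.01). The largest decreases were those of the ion channel gene CngA at −8.86 ± 0.09, whose second probe set did not pass (−0.08), CG33337 at −5.96 ± 0.13, thw at −5.40 ± 0.10, of whose 2 further probe sets 1 did not pass, and the circadian gene Clk at −4.99 ± 0.08. CG18754, CG15128, the adenylyl cyclase gene Ac76E and CG42324 followed with −4.39, −4.33, −4.33 and −3.92. Each limma adjusted p among these genes was at most 4.73e-08. The rule for named genes took only genes whose arrays did not overlap between the groups, which held for 46.8% of all probe sets. Means below the chemoreceptor bound of 5.28 understate changes. Among them were CG33337 at 3.88 in the jumu deficiency, and mwh at 4.86 and Gyc89Da at 4.43 in controls.

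The direct comparison of the mutants asks which effects differ between them, without the shared controls. Cell division genes were lower in the jumu deficiency than in the CHES-1-like null in 27 of 41 cases and higher in 4 (camera adjusted p = 1.12e-06, and adjusted p = 0.0888 with an estimated correlation), with pim at −1.91 ± 0.05 (SE) and twe at −2.20 ± 0.08. Neural genes were lower in 23 of 33 cases and higher in 2 (adjusted p = 2.53e-05, and 0.129 as the adjusted p with an estimated correlation), with grh, which is also in the epidermis list, at −1.41 ± 0.06 and repo, a glial gene, at −1.07 ± 0.06. Epidermis genes were lower in 21 of 33 cases and higher in 3 (adjusted p = 3.81e-05, and adjusted p = 0.0878 with an estimated correlation), with the polarity gene crb at −1.27 ± 0.05 and en at −1.49 ± 0.08. Germ cell genes were lower in 11 of 16 cases, with AGO3 at −3.18 ± 0.08 and tej at −2.59 ± 0.13 (adjusted p = 0.000141, and adjusted p = 0.139 with an estimated correlation). Against controls, 7 germ cell genes rose and 2 fell in the CHES-1-like null (camera adjusted p = 0.0567, and adjusted p = 0.469 with an estimated correlation). Haemocyte and fat body genes were higher in 16 of 29 cases, with Glt at 1.70 ± 0.06 and PPO2 at 0.98 ± 0.04 (adjusted p = 7.32e-05, and adjusted p = 0.0878 with an estimated correlation). Adjusted over the list alone, 28 division, 24 neural, 23 epidermis and 11 germ cell genes were lower and 16 haemocyte and fat body genes higher. Without replicate 3 of the CHES-1-like null, 28 division, 22 neural, 21 epidermis and 11 germ cell genes were lower and 17 haemocyte and fat body genes higher.

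Muscle founder and fusion genes were higher in the jumu deficiency than in the CHES-1-like null in 17 of 34 cases and lower in 5 (camera adjusted p = 0.005, and adjusted p = 0.0878 with an estimated correlation). The fusion receptor gene sns differed by 1.71 ± 0.04 (SE), as it fell by 0.88 ± 0.04 in the CHES-1-like null and rose by 0.84 ± 0.04 in the jumu deficiency. Adhesion and matrix genes were higher in 19 of 39 cases and lower in 7 (adjusted p = 0.00556, and adjusted p = 0.146 with an estimated correlation), with vkg at 1.24 ± 0.05. The Notch list, with Ocho at −0.41 ± 0.04, was lower in 15 of 24 cases (adjusted p = 0.0115, and adjusted p = 0.129 with an estimated correlation). The early patterning, trachea and salivary gland, and endoderm lists were also lower (adjusted p = 0.000156, 0.00144 and 0.00365, and adjusted p = 0.0888, 0.122 and 0.0878 with an estimated correlation), with bcd at −3.32 ± 0.04, pio at −1.13 ± 0.05 and fkh at −0.92 ± 0.09. The endoderm gene fkh is also in the trachea and salivary gland list. When adjusted over the list alone, 23 founder and fusion genes and 19 adhesion and matrix genes were higher. Likewise, 15 Notch, 16 early patterning, 16 trachea and salivary gland and 8 endoderm genes were lower. Without replicate 3 of the CHES-1-like null, 18 founder and fusion and 19 adhesion and matrix genes were higher, and 14 Notch, 16 early patterning, 16 trachea and salivary gland and 7 endoderm genes were lower. Over all probe sets 3173 were higher and 3291 lower. The highest, CHES-1-like apart, were Nach, Gr98b, mthl4, mwh, CG31176, beat-Ic, CG31601 and Ac78C, at 3.99 to 7.12, and the lowest were CngA, CG18754, Clk, CG15128, CG32299, CG8563, CG5568 and bcd, at −8.74 to −3.32, with the further probe sets of mwh and CngA not past the threshold.

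Genes changed in both mutants were compared by direction. The 2 mutants shared 668 higher genes, against 360.6 for independent lists of the same sizes, and 1015 lower genes, against 468.3. In opposite directions, 519 were higher in the CHES-1-like null and lower in the jumu deficiency, against 429.2, and 311 the reverse, against 393.4. Of the 1683 genes changed the same way, 918 did not differ past the threshold between the mutants, which does not show equal effects. The shared increases of largest mean were those of Gyc89Da, mwh, nkt, CG12885 and be. The mean of mwh rests mostly on the jumu deficiency, with 5.42 ± 0.08 (SE) against 0.44 ± 0.08 in the CHES-1-like null. The gene nkt rose by 2.47 ± 0.08 (SE) in the CHES-1-like null and 2.73 ± 0.08 in the jumu deficiency, and be rose by 2.42 ± 0.06 and 2.69 ± 0.06. The shared decreases were those of CG33337, CHES-1-like, thw, CG42324 and CG13003. CHES-1-like, deleted in its own null, changed by −7.97 ± 0.13 there and −0.61 ± 0.13 in the jumu deficiency. CG33337 changed by −5.85 ± 0.13 in the CHES-1-like null and −5.96 ± 0.13 in the jumu deficiency. Its means in both mutants lie below the chemoreceptor bound of 5.28, as do those of CG42324 at 5.27 and 5.22, so sizes of loss in the mutants cannot be compared for these genes. Across the 11982 genes, which are not independent replicates, the changes correlated at Pearson's r = 0.293 and Spearman's rho = 0.278. Unchanged groups simulated against the same controls gave r = 0.499, with 0.477 to 0.521 over 100 simulations, and 0 shared calls. With no change simulated, the shared control noise alone sets that r, so it is no yardstick for the r of the data. The covariance was 0.0419, against 0.00261 in the simulations. Since 3 controls cannot be parted into sets of several arrays each, part of the excess overlap may come from the shared controls. A difference particular to the control line would also change both mutants alike. The expectation for independent lists spreads calls evenly over all genes, dim ones included, so an excess alone does not show shared effects.

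**Figure D3:**
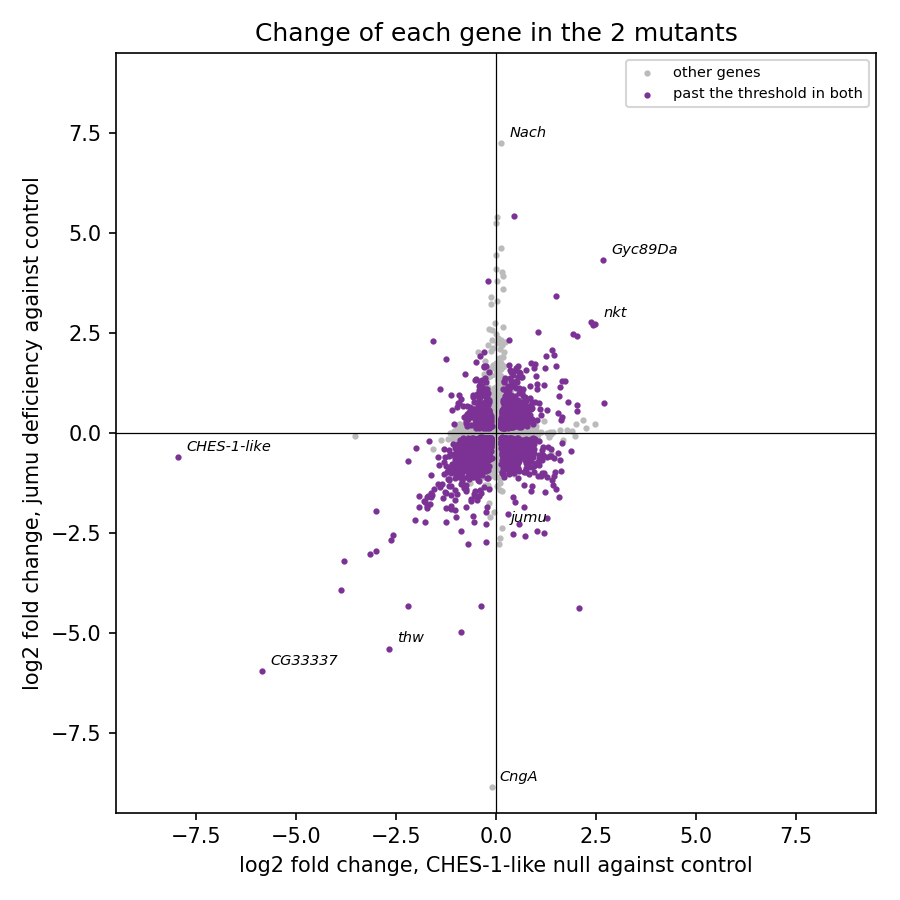
Log2 fold change against control of each of the 11982 genes in the CHES-1-like null (horizontal) and the jumu deficiency (vertical), with genes past an adjusted p of 0.05 in both comparisons in purple and the others in grey. CG33337 and nkt lie near the diagonal, and Nach and CngA lie near the vertical axis at 7.24 and −8.86.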

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

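The test of older embryos and the count of named genes changed in opposite directions were chosen after the results were seen. Among the targeted genes, htl and the gene lists, htl and the cell division list passed the threshold in both mutants in opposite directions and in the direct comparison of the mutants. The FGF receptor gene htl was lower in the CHES-1-like null and higher in the jumu deficiency, and differed by 0.85 on the log2 scale between them. The cell division list was higher in the CHES-1-like null and lower in the jumu deficiency, with a median difference of −0.333 between the mutants. With an estimated correlation the 3 list calls were lost (adjusted p = 0.126, 0.441 and 0.0888 for the CHES-1-like null, the jumu deficiency and the direct comparison), and that in the jumu deficiency was also lost with quantile normalization (0.0527) and without dim probe sets (0.13). Among the 184 genes named, which were picked for large changes or small p, 44 met the same criteria, and 830 of the 11982 genes changed in opposite directions in the mutants.

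For the lower cell division genes in the jumu deficiency, a candidate explanation is that its embryos were older when sorted. Muscle structural genes, which rise with age at these stages, had a median of −0.153 in the jumu deficiency, with a permutation p of 0.00803 from 100000 sign changes over the 23 genes, taken as independent, and −0.211 after centring each array, against what older embryos would show. That list's camera call was lost with an estimated correlation (adjusted p = 0.28), quantile normalization (0.068), centring (0.0577) and without dim probe sets (0.13). Early patterning genes, with 12 of 27 lower and 3 higher (camera adjusted p = 0.123), went the way older embryos would. So did the median of late epidermal and tracheal genes, at 0.159 with 6 of 14 higher and 1 lower, which was not tested. Of these late genes 13 belong to the epidermis or the trachea and salivary gland lists. Those whole lists had medians of −0.064 and −0.103 in the jumu deficiency and did not pass, so the late genes are weak evidence of age. Since these markers disagree, older embryos, effects of the deficiency, which were not tested, and a difference in genetic background cannot be told apart.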

How the results depend on the processing

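The alternatives of this part were planned, except for counts of list members without replicate 3 of the CHES-1-like null. Of 126 alternative values for CHES-1-like, jumu and htl, 125 kept their direction and side of the threshold, and the change of jumu in the CHES-1-like null passed with a variance trend and robust estimation (0.151, adjusted p = 0.036). Of 283 called results for named genes, 269 kept their call in every alternative run and 0 of the 302 reversed. The counts of probe sets in the order CHES-1-like null, jumu deficiency and direct comparison were 422 higher and 483 lower, 587 and 704, and 709 and 883 at a minimum of 1.5-fold. By Welch's test they were 1507 and 1706, 1685 and 1977, and 1834 and 1815. At an adjusted p of 0.01, 1714 and 1795 were higher in the CHES-1-like null and the jumu deficiency. The counts at 1.5-fold and at 0.01 follow from the stricter criteria. Welch's test takes the spread from the groups compared alone, without limma's moderation, and how much this lowered its counts was not tested. Median centring lowered every change in the jumu deficiency by the same amount, moving their median from 0.0203 to −0.0379, and left 1820 higher. Leaving out single arrays gave 2096 to 2457 higher and 2328 to 2607 lower, 2258 to 2555 and 2674 to 3004, and 2801 to 3106 and 2871 to 3261. The correlation of the mutant effects was 0.273 without dim probe sets, and 0.279 to 0.302 leaving out single arrays. The run next to jumu held 1 to 2 neighbours leaving out single arrays.

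Lists called numbered 1, 0 and 0 with an estimated correlation, against 8, 4 and 11, and 22, 19 and 19 with fry, which compares no list with other genes. The correlations estimated for the founder and fusion, muscle structural and endoderm lists were 0.003, 0.005 and −0.01, below the preset 0.01. In the CHES-1-like null their unadjusted camera p still rose, from 0.00424, 6.98e-07 and 0.0126 to 0.0199, 0.002 and 0.0398. A stronger correlation therefore does not account for the weaker results of these lists. The jumu deficiency had 2 with quantile normalization and 2 without dim probe sets, and 4 to 7 leaving out single arrays. Of the lists whose direction turned by fry, 2 passed the threshold: the Forkhead family was lower in the CHES-1-like null (adjusted p = 0.00114), with a mean of −0.351 that holds CHES-1-like itself and a median of 0.172, and epidermis was higher in the jumu deficiency (adjusted p = 0.00352), with a mean of 0.135 that holds mwh and a median of −0.064. The cause of the other changes was not tested. The replicate numbers did not pair the arrays, since same-numbered arrays deviated together at r of −0.136 to 0.15, and 2, 0 and 1 of 3 correlated best with their own number. With the replicate block, 2393 higher and 2612 lower, 2576 and 3006, and 2973 and 3112 probe sets were called, and the block changed the call of 4 named genes and 2 neighbours and of 0 lists. Probe sets near background limit the folds of genes that fell to it, and dim genes were left without a value where the filter removed them.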

Other observations

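The tests of cell share, embryo age and chromosomes in this part were chosen after the patterns were seen. Genes of the stress response went both ways. In the heat shock and dissociation stress list 6 of 21 genes rose and 1 fell in the CHES-1-like null (camera adjusted p = 0.198), and 10 rose and 4 fell in the jumu deficiency (adjusted p = 0.306). The glutathione transferase gene GstD1 rose in both, by 0.96 ± 0.06 (SE) and 1.71 ± 0.06, whereas the small heat shock gene Hsp26 rose by 0.72 ± 0.04 in the CHES-1-like null and fell by 0.48 ± 0.04 in the jumu deficiency. Among 10 dosage compensation and sex genes 5 fell in the jumu deficiency (adjusted p = 0.0594), including the splicing genes tra2 at −0.50 ± 0.05 and tra at −0.29 ± 0.04. In the CHES-1-like null 2 rose and 3 fell (adjusted p = 0.477), and without replicate 3 of that mutant 0 rose and 2 fell.

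Of the remaining lists, which did not pass in either mutant, the Hedgehog list had 3 of 11 higher and 3 lower in the CHES-1-like null (camera adjusted p = 0.962) and 1 higher and 4 lower in the jumu deficiency (adjusted p = 0.272). In the same order, the Notch list had 6 of 24 higher and 2 lower (adjusted p = 0.202), and 3 higher and 12 lower (adjusted p = 0.123). The adhesion and matrix list had 7 of 39 higher and 10 lower (adjusted p = 0.198), and 13 higher and 7 lower (adjusted p = 0.175). The Dpp and Tgf-beta list had 3 of 22 higher and 1 lower (adjusted p = 0.963), and 3 higher and 5 lower (adjusted p = 0.572). The protease gene tok changed by −0.80 ± 0.04 (SE) and −0.44 ± 0.04. Gonadal mesoderm had 2 of 7 higher and 2 lower in each mutant (adjusted p = 0.477 and 0.636), with eya up by 0.46 ± 0.08 and 0.68 ± 0.08. The Forkhead family had 6 of 17 higher and 3 lower (adjusted p = 0.477), and 2 higher and 6 lower (adjusted p = 0.284). The lower genes of this list include the targeted genes, CHES-1-like in each mutant and jumu in the jumu deficiency. Cytosolic ribosomal protein genes had 1 of 29 lower (adjusted p = 0.371), and a median of 0.013 in the jumu deficiency (adjusted p = 0.544). The call of that 1 gene was lost without replicate 3 of the CHES-1-like null. Hox genes and cofactors had 2 of 5 higher (adjusted p = 0.382), and 1 lower, Antp (adjusted p = 0.544). Counted with p adjusted over the list alone, the genes of these lists past the threshold in the CHES-1-like null numbered 4 higher and 4 lower for Hedgehog, 3 and 1 for Dpp and Tgf-beta, 3 and 2 for gonadal mesoderm, 6 and 3 for Forkhead, 6 and 1 for heat shock, 2 and 3 for dosage compensation and sex, and 2 and 0 for Hox. In the jumu deficiency they numbered 2 and 4, 3 and 6, 2 and 2, 2 and 6, 10 and 6, 0 and 6, and 0 and 1 in the same order. For Notch they numbered 6 and 2 in the CHES-1-like null and 3 and 13 in the jumu deficiency. For adhesion and matrix they numbered 7 and 11, and 14 and 9.

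In the CHES-1-like null, lists of other cell types were higher and muscle lists lower at the preset correlation. With an estimated correlation the epidermis, trachea and salivary gland, neural, endoderm, and founder and fusion calls were lost (adjusted p = 0.0713, 0.0894, 0.229, 0.136 and 0.119), and the muscle structural call was kept (adjusted p = 0.0479). If a lower share of mesodermal cells in the sort let in other types evenly, the markers of each type would rise about alike. The extra cells could also be mostly of 1 type, so unequal rises do not speak against a lower share. The epidermis, trachea and salivary gland, neural and endoderm genes in only 1 of these lists had medians of 0.404, 0.296, 0.247 and 0.16 (Kruskal-Wallis permutation p = 0.231 over 88 genes, taken as independent). The same permutation test gave p = 0.0361 over the 83 genes above the dim cutoff, and the 8 measured pan-mesodermal genes had a median of −0.0965, with 3 lower and 1 higher. The outcome turns on the filter, and the test rests on that evenness. A lower share of mesodermal cells, younger embryos and effects of CHES-1-like itself, which were not tested, therefore cannot be told apart. A difference in genetic background cannot be told apart from these either. Genes of late epidermal and tracheal differentiation had a median change of 0.236, but 13 of the 14 belong to the lists that rose, so this says nothing about age, and the lower muscle structural genes (median −0.541) are also what younger embryos would show. So are the early patterning genes, with 14 of 27 higher and 1 lower (camera adjusted p = 0.00175, and adjusted p = 0.136 with an estimated correlation).

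The share of chromosome 2 among changes of at least 2-fold may reflect different chromosomes in the lines compared. Of the genes changed in the CHES-1-like null alone 29.6% of 98 lay on chromosome 2, against 52.8% of 246 in the jumu deficiency alone and 39.0% of all measured genes. Rotating the calls along the order of the 11888 genes, which keeps neighbours together, gave a permutation p = 0.0894 for that difference of 23.3 percentage points, which did not pass. On chromosomes 2, 3, X and 4, 1.06%, 1.65%, 2.30% and 7.69% of the measured genes changed at least 2-fold in the CHES-1-like null and 3.24%, 2.56%, 2.24% and 7.69% in the jumu deficiency, with 5 of 65 genes on chromosome 4 in each. Each group is a single genotype, so line background and effects of the mutations cannot be told apart from these shares.

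With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 5442, 6035 and 6464 probe sets in the CHES-1-like null, the jumu deficiency and the direct comparison, was the 1 split with as many calls in each, and the highest other split called 0.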
